A study of Mus musculus with 9 samples.

How the data were processed

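Total RNA from perigonadal white adipose tissue of mice aged 4 months was measured on Affymetrix exon arrays in 1 colour, with fragmentation and biotin labelling by the WT Terminal Labeling Kit, per the labels' protocols. The authors deposited log2 values, 1 per probe set and array, for 229581 probe sets on 9 arrays, with no value missing. How the authors normalized and summarised these log2 values, and with what software, is not given in the sources used here. The submitters' processing notes name the genome build mm9. The lowest and highest deposited values lie close together on the 9 arrays, while the medians differ between groups, from 6.57 in G609G to 7.23 in LCS. A uniform offset left by normalization would shift every gene of a group alike. The scale is read from the values as log2; an offset between groups cannot be assigned to the tissue or to the normalization from these values alone. The submitters' design text speaks of 10 samples, and 9 arrays were analysed here.

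Arrays were assigned to WT, G609G and LCS by their titles, with 3 arrays each and the replicate numbers of the titles. Within groups the arrays correlated across probe sets with r from 0.972 to 0.990, against 0.904 to 0.919 between WT and G609G and 0.965 to 0.971 between WT and LCS. No pair of arrays held more than 1.89% identical values at the 2 deposited decimals, so no array was treated as a duplicate. The labels do not say what the replicate numbers share. Deviations from the group means of same-numbered WT and G609G arrays correlated with r = 0.168, 0.145 and 0.337, each over 0.1, so these numbers were taken to pair the arrays of that comparison. Over all groups only 2 of 9 arrays correlated best with their own number, so the pairing is uncertain. The main tests do not use it, and a replicate block is given as an alternative.

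Gene names came from the platform annotation of the probe sets. Exactly 1 symbol was given for 208397 probe sets, several for 3965 and none for 17219, and genes were formed only from the first. Of 16299 symbols, 14132 were current, 2161 matched a synonym and 6 matched nothing in a RefSeq gene table of assembly GRCm38.p6, which was used for names only. Since that assembly is not the build named for these values, no coordinates are printed. Probe set values were summarised per gene by median polish (at most 10 rounds). Genes with at least 3 probe sets and a mean above the 25th percentile were tested, 11342 in all.

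Gene changes were tested with limma (lmFit and eBayes with a trend) over the 9 arrays, with Benjamini-Hochberg adjustment and a threshold of 0.05, for G609G minus WT, LCS minus WT and G609G minus LCS. Probe sets above the 25th percentile were tested against the other probe sets of their gene with limma's diffSplice, 156218 in 12923 genes. Gene lists fixed before the data were examined, 36 in number with 926 different symbols, of which 697 were tested, covered adipocytes, lipid metabolism, stress responses, other cell types of the depot and neighbouring tissues. Those with at least 3 tested genes, 35 lists, were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Every adjusted p printed comes from these tools or, for the splicing index, from limma's lmFit and eBayes with a trend on probe set minus gene values. R 4.3.3, limma 3.58.1, the data.table package (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9 were used.

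Genes named in the text were chosen by a rule set before the data were examined: the 10 largest rises and 10 largest falls per comparison among called genes whose groups do not overlap, without predicted names and olfactory or vomeronasal receptors; up to 4 members with the lowest p in each list; a fixed set around Lmna and adipocyte biology; and the 5 probe sets with the lowest diffSplice p, 1 per gene. Of the fixed set, Lmnb1, Xist, Ddx3y and the newer symbol Adgre1 had no probe set with that single symbol and were not analysed here. Genes of the closing part's added marker lists are named as such. Dio2, Elovl3 and Otop1 were named after their values were seen.

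Alternatives set before the data were examined covered the summary, quantile normalization, centring, filters, the variance model, the arrays entering the fit, a replicate block, an unpaired Student comparison at a fold of 1.5 as the methods of the series describe (the methods' t-test), and leaving out each array. After the data were examined 4 alternatives were added. The first centred the gene values on each array's median over the tested genes. Its calls were seen, and because it left a median log2 fold of 0.15 in G609G minus WT, the second was added, which subtracts each array's median deviation from the gene means and leaves -0.01; folds called relative to the median gene come from it. The third was the splicing index, and the fourth a replicate block on the WT and G609G arrays alone.

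The steps were tested on simulated data with known changes. In G609G minus WT over 11342 genes, 88% of planted log2 changes of 0.5 and 100% of changes of 1 were recovered, with 4.25% false calls. For single probe sets in G609G minus WT over 12923 genes, diffSplice recovered 8.82% of changes of 0.5, 56.1% of changes of 1 and 100% of changes of 2, with 306 false calls. The splicing index recovered 0%, 19.7% and 72.7%, with 1 false call. Groups of 3 arrays allow no exact permutation p under 0.1 for a single gene.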

Results

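Exon-level microarrays measured total RNA of perigonadal white adipose tissue from mice aged 4 months. White adipose tissue is the fat-storing tissue, and its perigonadal depot lies next to the gonads and, in males, the epididymis. The 9 arrays fall into 3 groups of 3: wild type (WT), mice homozygous for the G609G allele of Lmna, and mice homozygous for the LCS allele. Lmna encodes the nuclear lamins A and C. G609G is known as a progeria allele from which a shortened lamin A (progerin) is spliced, and LCS is known as an allele of the same gene that yields lamin C without lamin A. Each array gave a log2 intensity for 229581 probe sets. The median over probe sets was 7.21 ± 0.06 in WT, 6.57 ± 0.06 in G609G and 7.23 ± 0.04 in LCS (SD, n = 3 arrays each). The number of arrays limits the precision. Where a group's mean lies under the intensity filters, 5.09 for genes and 5.01 for probe sets, the deposited log2 fold may understate the size of the change, and a fold rescaled between arrays, as given below for G609G, is not a bound on it. Nothing in the labels ties each array to its own animal beyond the word biological, so the p-values measure only the spread between these samples, which may be technical.

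Lmna itself was examined first, since it is the mutated gene. Of its 17 probe sets, 16 passed the intensity filter and were tested against the other probe sets of the gene. Probe set 5039122 had a mean of 9.02 ± 0.29 in WT, 8.10 ± 0.29 in G609G and 4.65 ± 0.46 in LCS (SD, n = 3), with the LCS mean under the filter. Probe set 4817758 was also lowest in LCS, at 4.39 ± 0.16 against 6.47 ± 0.09 in WT and 7.00 ± 0.30 in G609G. Probe set 4479405 was low in both mutants, at 5.97 ± 0.27 in G609G and 5.91 ± 0.20 in LCS against 8.48 ± 0.21 in WT. These probe sets passed the diffSplice test against the rest of the gene in LCS minus WT, with adjusted p = 1.45e-34, 4.06e-11 and 1.31e-16 in the order named. In G609G minus WT, 4479405 was lower than the rest (adjusted p = 6.08e-14) and 4817758 higher (adjusted p = 3.78e-08). In total 3 Lmna probe sets were called in G609G minus WT, 10 in LCS minus WT and 11 in G609G minus LCS, or 2, 3 and 9 with a splicing index that gives each probe set its own variance, an alternative chosen after seeing the data. With only the probe sets above the 50th percentile tested, 1 was called in G609G minus WT and 7 in G609G minus LCS. Positions of the probe sets within the gene were not used here. Summarised over its probe sets, Lmna did not pass the limma test in LCS minus WT (log2 fold 0.09, SE 0.09, adjusted p = 0.499), and a plain mean of probe sets gave -0.47 there.

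**Figure D1:**
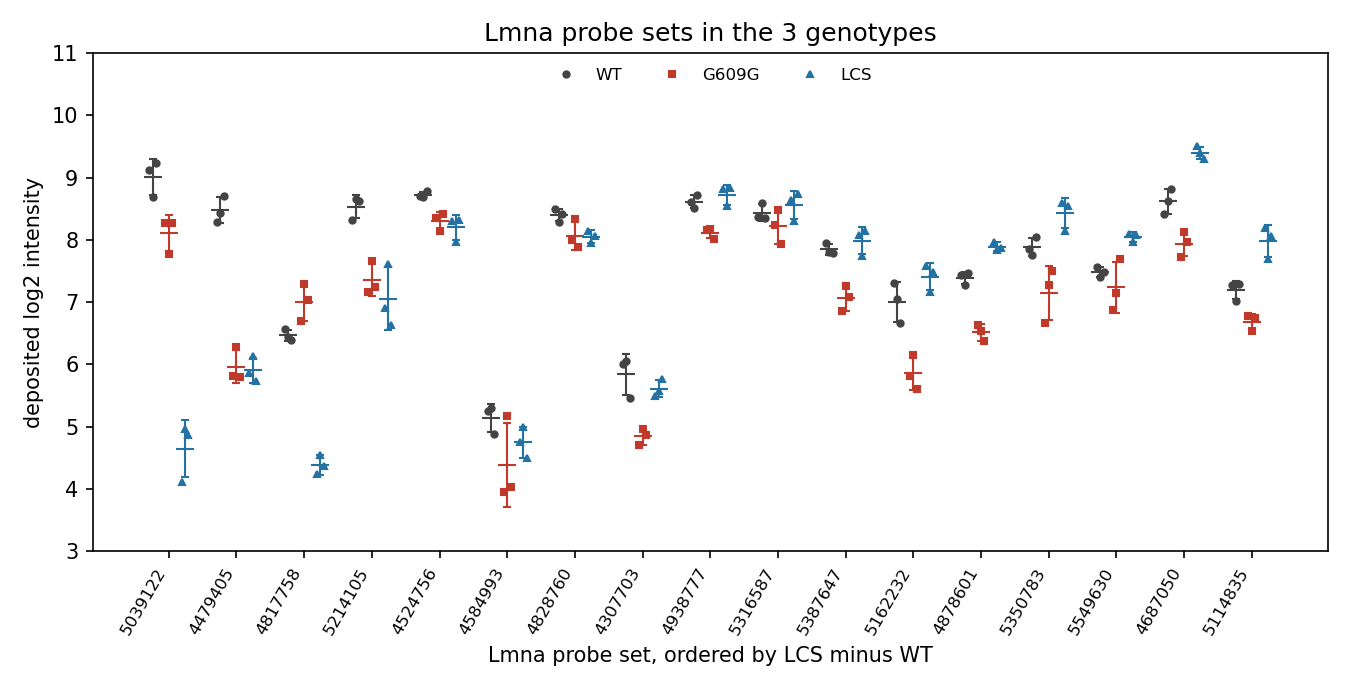
Deposited log2 intensity (vertical axis) of the 17 Lmna probe sets (horizontal axis, ordered by LCS minus WT), with 1 point per array and bars for the mean ± SD of 3 arrays. Probe set 5039122 averages 9.02 in WT and 4.65 in LCS, and 4479405 averages 8.48 in WT, 5.97 in G609G and 5.91 in LCS.

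The comparison of G609G with WT addresses which transcripts differ in the fat samples of the progeria model. Skeletal muscle transcripts were higher in G609G: the fast troponin Tnnt3 had a mean of 13.27 ± 0.04 against 5.54 ± 0.14 in WT, and the sarcoplasmic calcium pump Atp2a1 12.78 ± 0.06 against 4.75 ± 0.08 (SD, n = 3). Epididymal transcripts were lower, among them the lipocalin Lcn8 (4.59 ± 0.15 against 12.74 ± 0.05) and the glutathione peroxidase Gpx5 (5.47 ± 0.65 against 13.36 ± 0.03). Lep, which encodes the adipocyte hormone leptin, had a mean of 4.76 ± 0.08 against 10.63 ± 0.06. Macrophage and extracellular matrix transcripts were lower, and transcripts of the fasting and glucocorticoid response were higher, including the cell cycle inhibitor Cdkn1a (11.55 ± 0.10 against 8.93 ± 0.02). The epididymis and testis, macrophage and extracellular matrix list calls were lost, with adjusted p = 0.0786, 0.569 and 0.366 with an estimated correlation, and the skeletal muscle and the fasting and glucocorticoid calls held.

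As deposited, the G609G values were lower for most genes, with a median log2 fold of -0.47 over the 11342 genes tested. The limma test called 937 genes higher and 8083 lower at an adjusted p under 0.05, and 419 higher and 4676 lower at a fold of 1.5 or more. Relative to the median gene, a scaling chosen after seeing the data, 3858 genes were higher and 4160 lower. An earlier added scaling, which set the arrays' medians equal, gave 5204 higher and 3087 lower, and quantile normalization gave 3519 and 4304. The division into higher and lower therefore depends on the scaling. The log2 folds that follow for G609G are relative to the median gene, and the deposited folds are 0.46 lower against WT, so that the scaling offset is -0.46. The groups did not overlap for 79.2% of genes as deposited and 71.6% relative to the median gene, where chance gives 10%.

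In the skeletal muscle list 15 of 15 tested genes rose under either scaling and when adjusted over the list alone. Besides Tnnt3 (8.20, SE 0.07) and Atp2a1 (8.49, SE 0.08), these included the fast myosin Myh4 (7.84, SE 0.08), the troponin Tnni2 (7.63, SE 0.08), the calcium-binding protein Pvalb (7.76, SE 0.08) and the creatine kinase Ckm (6.94, SE 0.12). The WT means of Atp2a1, Myh4 and Pvalb lay under the filter, and their deposited folds were 8.03, 7.37 and 7.29. The list's camera test held with a preset correlation (adjusted p = 2.02e-40) and gave adjusted p = 0.00192 with an estimated correlation. In the epididymis and testis list 19 of 20 genes fell as deposited and adjusted over the list alone, and 18 fell relative to the median gene. Lcn8 (-7.68, SE 0.07), Gpx5 (-7.42, SE 0.21), the cystatin Cst11 (-6.19, SE 0.05) and Rnase10 (-5.72, SE 0.09) were among those that fell most, while Lcn5 changed by -1.44 (SE 0.03). For the list camera gave adjusted p = 1.2e-06, and adjusted p = 0.0786 with an estimated correlation.

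Among mature adipocyte genes 20 of 22 fell as deposited and adjusted over the list alone, and 14 fell and 6 rose relative to the median gene. Lep changed by -5.41 (SE 0.05), the natriuretic peptide clearance receptor Npr3 by -2.78 (SE 0.04), retinol-binding protein Rbp4 by -1.24 (SE 0.03) and hormone-sensitive lipase Lipe by -0.54 (SE 0.03). The adipokine Adipoq (-0.34, SE 0.05), the adipogenic factor Cebpa (-0.73, SE 0.06) and fatty acid synthase Fasn (-1.61, SE 0.03) also fell. The adipogenic receptor Pparg was -0.14 as deposited and 0.32 relative to the median gene, and the lipase Pnpla2 -0.14 and 0.33, so the direction of both turns with the scaling. The deposited Pparg call was lost without WT replicate 3 (adjusted p = 0.0879) or G609G replicate 2 (adjusted p = 0.0796). In the lipolysis list 9 of 10 genes fell as deposited and adjusted over the list alone, led by the protein kinase A subunit Prkar2b (-2.31, SE 0.04), and 7 fell relative to the median gene. Of 25 genes of fatty acid and triglyceride synthesis 19 fell and 6 rose as deposited and adjusted over the list alone, without a camera call (adjusted p = 0.249), and the triglyceride synthesis enzyme Dgat2 fell by 2.39 on the log2 scale. The camera test gave adjusted p = 0.000285 for mature adipocyte and 0.013 for lipolysis, and adjusted p = 0.366 for both with an estimated correlation. With the replicate block on the WT and G609G arrays alone, an alternative chosen after seeing the data, the lipolysis call was lost (adjusted p = 0.0744).

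In the macrophage list 29 of 30 genes fell as deposited, 30 adjusted over the list alone and 24 relative to the median gene, with 2 higher. The lysozyme Lyz2 (-0.76, SE 0.04), the receptor Csf1r (-1.07, SE 0.05), the proton pump subunit Atp6v0d2 (-3.15, SE 0.12) and the marker Emr1 (-1.56, SE 0.08) were among them. In the extracellular matrix list 35 of 38 genes fell as deposited and adjusted over the list alone, and 29 relative to the median gene, including Sparc (-1.04, SE 0.03), Nid1 (-1.11, SE 0.03) and Thbs1 (-1.99, SE 0.04). Of 23 adipocyte progenitor and fibroblast genes, 20 fell as deposited, 21 adjusted over the list alone and 16 relative to the median gene, with Col15a1 at -2.57 (SE 0.14) and Cd248 at -2.25 (SE 0.12). Camera called these lists lower (adjusted p = 0.000208, 5.81e-05 and 0.0379), and gave adjusted p = 0.569, 0.366 and 0.608 with an estimated correlation. The adipocyte progenitor and fibroblast call was also lost with that replicate block (adjusted p = 0.0788).

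The fasting and glucocorticoid list had 15 of 18 genes higher as deposited and adjusted over the list alone, and 16 relative to the median gene. Gadd45g (4.48, SE 0.06), Errfi1 (2.89, SE 0.05) and Cdkn1a (3.08, SE 0.04) rose, and the acute-phase protein Lcn2 fell (-1.25, SE 0.04). The list had a camera adjusted p = 8.71e-20, and adjusted p = 0.0437 with an estimated correlation. In the p53 target list 7 of 28 genes rose and 16 fell as deposited and adjusted over the list alone, against 14 and 7 relative to the median gene. Its deposited median was -0.24 and its mean -0.01, while camera called it higher (adjusted p = 0.00487, and adjusted p = 0.366 with an estimated correlation). The members that rose included Trp53inp1 (3.38, SE 0.06), Sesn1 (2.69, SE 0.04) and the antiproliferative Btg2 (1.89, SE 0.06). Among immediate early genes, whose transcription responds fast to stimuli, 11 of 23 rose and 3 fell as deposited and adjusted over the list alone, and 19 rose and 1 fell relative to the median gene. Nr4a3 rose (4.89, SE 0.06) and Egr2 fell (-2.72, SE 0.09), and camera gave adjusted p = 7.63e-10, and adjusted p = 0.116 with an estimated correlation. Of 17 clock genes 8 were higher and 5 lower as deposited and adjusted over the list alone, and 13 and 3 relative to the median gene, with Npas2 (2.52, SE 0.05), Nfil3 (3.48, SE 0.15) and Arntl (2.01, SE 0.06) higher and Bhlhe41 lower (-1.92, SE 0.10). The clock list had a camera adjusted p = 1.2e-06, and adjusted p = 0.366 with an estimated correlation.

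Genes of glycolysis and of brown and beige adipocytes were also called higher by camera. In glycolysis 7 of 16 genes rose and 5 fell as deposited and adjusted over the list alone, and 11 and 4 relative to the median gene, led by the muscle-type phosphofructokinase Pfkm (3.50, SE 0.05), with Aldoa at 1.10 (SE 0.03); camera gave adjusted p = 1.76e-05, and adjusted p = 0.366 with an estimated correlation. In the brown and beige list 7 of 17 rose and 7 fell as deposited and adjusted over the list alone, and 10 and 2 relative to the median gene, with Cox8b (2.79, SE 0.04), Fabp3 (1.81, SE 0.10), the coactivator Ppargc1a (1.57, SE 0.09) and Cidea (0.74, SE 0.11) higher relative to the median gene. Muscle also expresses Cox8b, Fabp3 and Ppargc1a, and of 26 measured genes of the list those under the filter, Ucp1 among them, were not tested. The list's camera call held with both correlations (adjusted p = 2.73e-05, and adjusted p = 0.0437 with an estimated correlation). As deposited, Cidea lost its call without WT replicate 2, WT replicate 3 or G609G replicate 3, with adjusted p from 0.0812 to 0.166, and with the replicate block on the WT and G609G arrays alone (adjusted p = 0.0726). Ucp1, the uncoupling protein of brown fat, lay below the filter on dim genes; fitted without it, its deposited log2 fold was -1.59 (SE 0.13, adjusted p = 2.58e-07). Zmpste24, the protease that processes prelamin A, changed by -0.25 (SE 0.07, adjusted p = 0.00842), and Igfbp3 by 3.24 (SE 0.05). Lmna was lower as deposited (-0.60, SE 0.09, adjusted p = 3.25e-05) but not relative to the median gene (-0.14, adjusted p = 0.151). Camera also called mitochondrial biogenesis (5 of 22 genes higher and 11 lower, 5 and 10 adjusted over the list alone), oxidative phosphorylation (4 and 31 of 59, 4 and 29 adjusted over the list alone), endothelial (6 and 11 of 19, also adjusted over the list alone) and smooth muscle and pericyte (6 and 8 of 17, also adjusted over the list alone) higher than other genes, although their deposited medians and means were negative. Relative to the median gene 11 and 3, 47 and 4, 13 and 4, and 10 and 3 genes were higher and lower. These calls had adjusted p = 0.0235, 0.043, 0.028 and 0.00473, and adjusted p = 0.633, 0.755, 0.737 and 0.603 with an estimated correlation. The oxidative phosphorylation call was lost with that block (adjusted p = 0.0713). Camera called 18 of 35 lists in this comparison and 3 with an estimated correlation, and fry, which does not compare a list with other genes, 32. Regrouping the 6 arrays called up to 14 lists. Each regrouping mixes the genotypes in unequal shares and so keeps part of the real difference, so it gives no chance level. Since only 3 calls held with an estimated correlation, the number of lists called says little by itself. Skeletal muscle transcripts, at a list median of 6.55, were higher in the same arrays as every gene group described for G609G. Whether muscle RNA gave part of the other rises, such as those of the fasting and glucocorticoid list, was not tested.

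**Figure D2:**
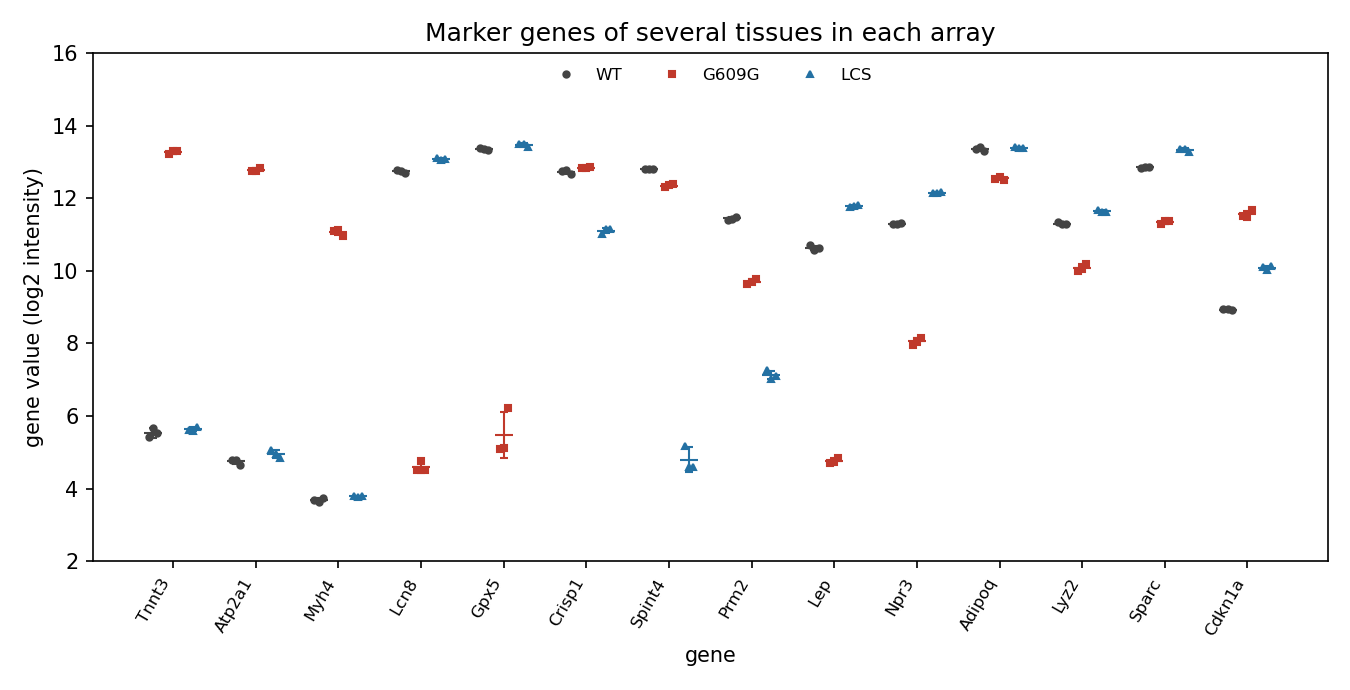
Gene values in log2 intensity (vertical axis) of 14 genes (horizontal axis), with 1 point per array and bars for the mean ± SD of 3 arrays per group. Tnnt3 averages 13.27 in G609G and 5.54 in WT, Lcn8 12.74 in WT and 4.59 in G609G, Spint4 12.80 in WT and 4.80 in LCS, and Lep 10.63 in WT, 4.76 in G609G and 11.78 in LCS.

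The comparison of LCS with WT addresses which transcripts differ in the fat samples of mice with the LCS allele. The transcript with the largest fall among the named genes was Spint4, with a mean of 4.80 ± 0.33 against 12.80 ± 0.01 in WT, and the sperm protamine Prm2 fell to 7.13 ± 0.12 against 11.44 ± 0.04 (SD, n = 3). Lep was higher, at 11.78 ± 0.03 against 10.63 ± 0.06. Extracellular matrix, macrophage, fibroblast and immediate early transcripts were higher by smaller amounts. These list calls were lost, with adjusted p = 0.294, 0.489, 0.308 and 0.308 with an estimated correlation. The limma test called 2554 genes higher and 1478 lower of 11342, with a median log2 fold of 0.05, and 2526 and 2007 relative to the median gene. The groups did not overlap for 52.2% of genes as deposited and 57.8% relative to the median gene, where chance gives 10%. At a fold of 1.5 or more, 445 genes were higher and 528 lower, and with array weights the test called 6376 genes in place of 4032.

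Other large falls were the inhibitor-domain gene Wfdc13 (-6.44, SE 0.09), the testis fatty acid-binding protein Fabp9 (-5.61, SE 0.10), the defensin Defb22 (-5.51, SE 0.13), the sperm protein Crisp2 (-5.36, SE 0.10) and the G protein-coupled receptor Gpr82 (-5.25, SE 0.14). Whether Spint4 and these transcripts came from fat or from other tissue in the samples was not tested. The epididymis and testis list went both ways, 9 genes higher and 8 lower of 20 (10 and 8 adjusted over the list alone), and camera did not call it (adjusted p = 0.116). Its median log2 fold was 0.10 and its mean -0.58. Rnase9 (-2.88, SE 0.05), Crisp1 (-1.62, SE 0.04) and Lcn5 (-1.52, SE 0.03) were among those that fell. The largest rises were the choline transporter Slc5a7 (2.94, SE 0.11), Sectm1b (2.14, SE 0.11), Scube1 (1.84, SE 0.10) and the fatty acid elongase Elovl4 (1.82, SE 0.10).

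In the mature adipocyte list 14 of 22 genes rose and 1 fell (17 and 2 adjusted over the list alone), with Lep at 1.14 (SE 0.06), Npr3 at 0.85 (SE 0.05), Itga7 at 1.23 (SE 0.09) and Pnpla3 at 1.18 (SE 0.07). Of 10 lipolysis genes 8 rose, also adjusted over the list alone, including the lipase coactivator Abhd5 (0.46, SE 0.06) and Prkar2b (0.32, SE 0.03). For these lists camera gave adjusted p = 0.000111 and 0.00337, and adjusted p = 0.308 for both with an estimated correlation. Adipoq (0.03, adjusted p = 0.343), Fasn (-0.01, adjusted p = 0.855), Cebpa (0.17, adjusted p = 0.0511) and Zmpste24 (0.15, adjusted p = 0.179) did not pass the limma test, although Cebpa did without WT replicate 3 (adjusted p = 0.0432). Pnpla2 was 0.08 (adjusted p = 0.00742, and 0.208 relative to the median gene) and Pparg -0.14 (adjusted p = 0.0407). Pparg lost its call without WT replicate 1, WT replicate 3 or any LCS replicate, with adjusted p from 0.073 to 0.163.

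Of 38 extracellular matrix genes 30 rose and 3 fell (31 and 3 adjusted over the list alone), including the basement membrane collagen Col4a2 (1.20, SE 0.07), the microfibril protein Fbn1 (0.97, SE 0.05) and Sparc (0.48, SE 0.03). Of 30 macrophage genes 20 rose and 1 fell (21 and 2 adjusted over the list alone), with the scavenger receptor Cd163 at 0.85 (SE 0.07), the complement component C1qb at 0.68 (SE 0.06), Lyz1 at 0.59 (SE 0.05) and Emr1 at 0.38 (SE 0.10). Of 23 adipocyte progenitor and fibroblast genes 15 rose and 1 fell (16 and 1 adjusted over the list alone), among them Mfap5 (0.98, SE 0.06) and Pi16 (0.90, SE 0.08). Camera called these lists higher (adjusted p = 3.56e-09, 1.22e-05 and 0.000164), and gave adjusted p = 0.294, 0.489 and 0.308 with an estimated correlation. Endothelial genes (14 of 19 higher, 15 adjusted over the list alone) and mesothelial genes (12 of 17 higher, also adjusted over the list alone) were called as well, with Kdr at 0.56 (SE 0.07), Cdh5 at 0.36 (SE 0.04), Msln at 0.88 (SE 0.10) and Efemp1 at 0.40 (SE 0.03). Their camera values were adjusted p = 0.00118 and 0.00739, and adjusted p = 0.634 and 0.489 with an estimated correlation.

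Immediate early genes rose in 17 of 23 cases (19 adjusted over the list alone), with Cyr61 at 1.01 (SE 0.09) and Ier3 at 0.99 (SE 0.08). Fasting and glucocorticoid genes rose in 14 of 18 cases, also adjusted over the list alone, including Cdkn1a (1.15, SE 0.05), Pdk4 (0.59, SE 0.03), Mt2 (0.52, SE 0.02) and Angptl4 (0.52, SE 0.04). Genes linked to senescence and its secretions rose in 9 of 14 cases (10 adjusted over the list alone), with Serpine2 at 1.35 (SE 0.09) and Igfbp3 at 0.72 (SE 0.07). Their camera values were adjusted p = 1.22e-05, 7.86e-09 and 0.000595, and adjusted p = 0.308, 0.294 and 0.279 with an estimated correlation. Red cell genes were lower, 2 of 3 also adjusted over the list alone, with the heme synthesis enzyme Alas2 at -1.18 (SE 0.08) and Bpgm at -0.72 (SE 0.12). Oxidative phosphorylation genes were lower in 12 of 59 cases and higher in 5, also adjusted over the list alone, with Cox6b1 at -0.56 (SE 0.04) and Ndufs6 at 0.49 (SE 0.05). For red cell and oxidative phosphorylation genes camera gave adjusted p = 0.0114 and 0.0453, and adjusted p = 0.294 and 0.788 with an estimated correlation. In the brown and beige list, not called by camera (adjusted p = 0.235, median 0.02, mean -0.12), Fabp3 (-1.13, SE 0.11), Ppargc1a (-0.81, SE 0.10) and Cidea (-0.56, SE 0.11) fell, and Ucp1, fitted without the filter on dim genes, had a log2 fold of -1.74 (SE 0.13, adjusted p = 6.18e-07). Camera called 12 of 35 lists here and 0 with an estimated correlation, while fry called 21. Regrouping the 6 arrays, which again keeps part of the real difference, called up to 10 lists. The sperm protamine Prm2, at -4.31, was lower in the same arrays as every gene group described for LCS.

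**Figure D3:**
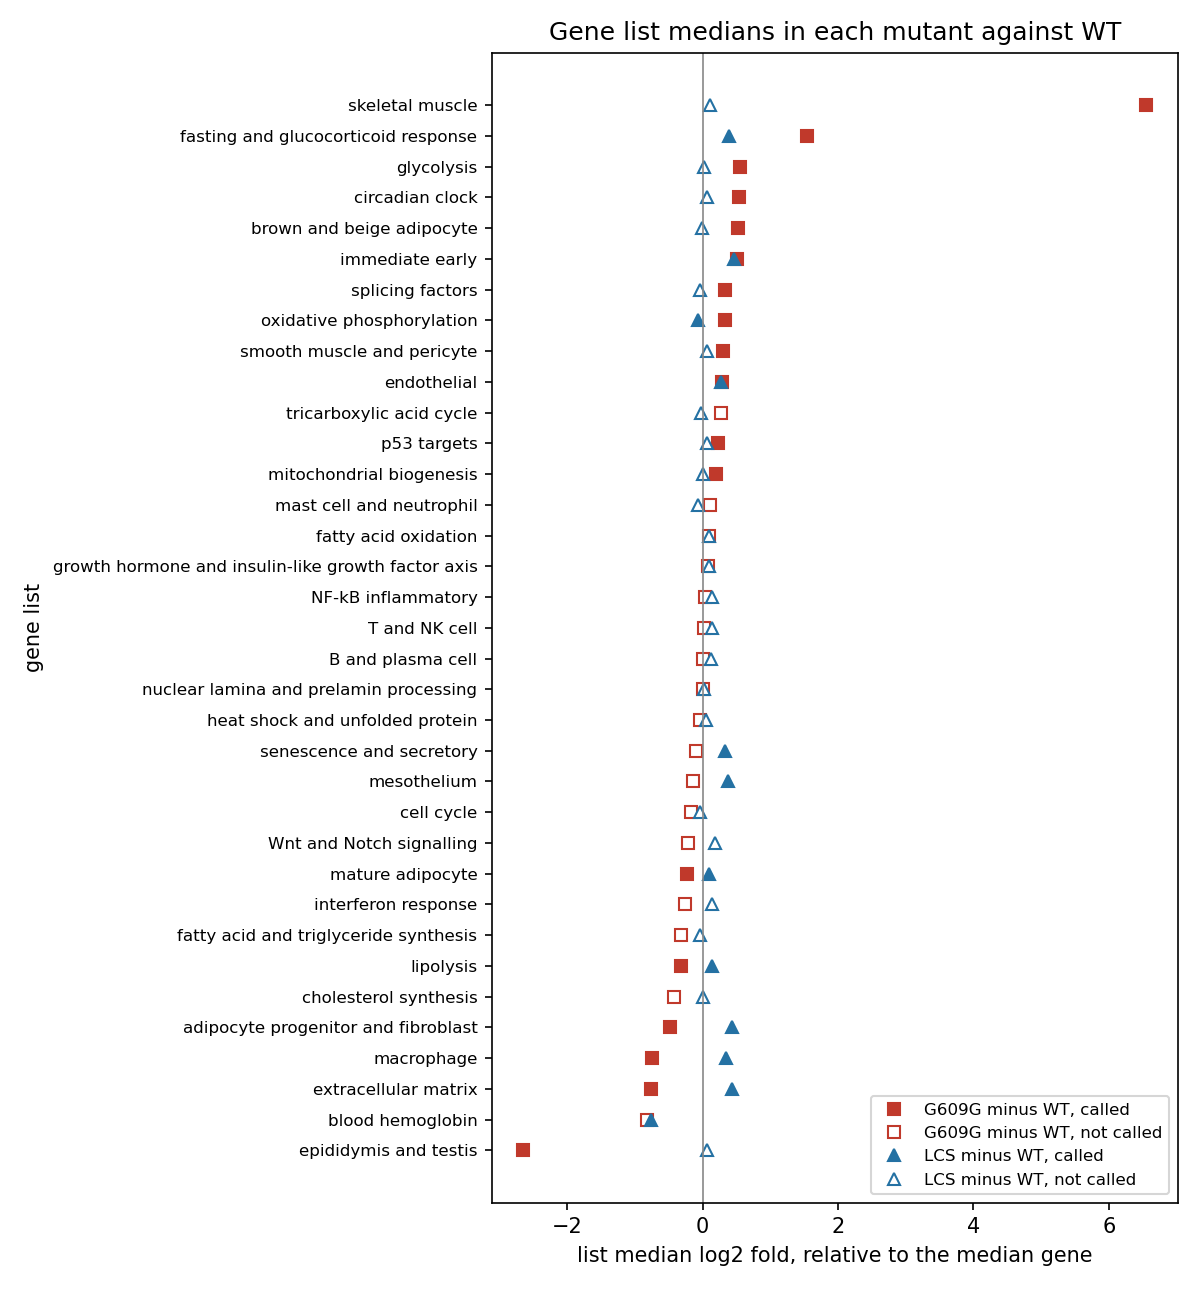
Median log2 fold of the tested genes of 35 gene lists (vertical axis), relative to the median gene (horizontal axis), for each mutant against WT; filled symbols mark lists that camera called with the preset correlation. Skeletal muscle lies at 6.55 in G609G and 0.10 in LCS, epididymis and testis at -2.65 and 0.07, macrophage at -0.75 and 0.34, and extracellular matrix at -0.77 and 0.43.

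The direct comparison of the mutants asks which transcripts differ between the samples of the 2 Lmna genotypes. An effect of the alleles on fat was not told apart from differences in other tissue within the samples. Muscle transcripts were higher in G609G (Tnnt3 8.13, SE 0.07, and Atp2a1 8.32, SE 0.08), as were Spint4 (8.05, SE 0.11) and Wfdc13 (6.77, SE 0.09). Lcn8 (-7.99, SE 0.07), Rnase10 (-7.00, SE 0.09), Ly6g5c (-7.63, SE 0.09), Lep (-6.52, SE 0.05) and Npr3 (-3.60, SE 0.04) were lower in G609G. The inflammatory cyclooxygenase Ptgs2 (4.21, SE 0.04) and Nfkbia (1.56, SE 0.03) were higher and the natural killer receptor Klrb1c lower (-4.21, SE 0.15). These log2 folds are relative to the median gene, with a scaling offset of -0.50. Of 30 macrophage genes 30 were lower in G609G, also adjusted over the list alone, and 26 relative to the median gene; camera gave adjusted p = 1.72e-05, and adjusted p = 0.495 with an estimated correlation. Of 38 extracellular matrix genes 33 were lower, also adjusted over the list alone, with camera adjusted p = 1.52e-05, and adjusted p = 0.495 with an estimated correlation. Cdkn1a (1.96, SE 0.04), Ppargc1a (2.42, SE 0.09) and Cidea (1.34, SE 0.11) were higher in G609G, and Cebpa (-0.86, SE 0.06), Fasn (-1.56, SE 0.03), Adipoq (-0.34, SE 0.05), Zmpste24 (-0.37, SE 0.07) and Emr1 (-1.90, SE 0.08) lower. Pparg did not pass the limma test as deposited (adjusted p = 0.959) and was 0.49 relative to the median gene, and Pnpla2 was -0.22 and 0.28. Lmna was -0.69 as deposited (adjusted p = 7.69e-06) and -0.20 relative to the median gene (adjusted p = 0.0511). The limma test called 1064 genes higher and 7998 lower as deposited, of which 495 and 4897 had a fold of 1.5 or more, and 4186 and 4182 relative to the median gene, with a deposited median of -0.48 and non-overlapping groups for 81.3% of genes, or 75.3% relative to the median gene, where chance gives 10%. Camera called 16 of 35 lists and 2 with an estimated correlation, fry 32, and regrouping the 6 arrays called up to 12. These regroupings keep part of the real difference too.

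The mutants' changes against WT were then set side by side. Both mutants were higher for 299 genes and lower for 1222, while 124 were higher in G609G and lower in LCS and 1942 the reverse. Independent lists of these sizes would give 211, 1053, 122 and 1820. Relative to the median gene the observed counts were 777, 1003, 561 and 1183 against 859, 736, 683 and 926, so genes higher in both lay above independence as deposited and below it on the relative scale. In 20 simulations of unchanged groups against the same WT arrays at most 1 gene was called higher in both and 0 lower in both. The correlation of log2 folds across genes, which are not independent replicates, was 0.134 against a simulated mean of 0.502, and the covariance 0.0518 against 0.00449. The simulated groups hold no change, so the shared WT arrays alone set their correlation. It therefore does not show whether the mutants are more or less alike than expected. The 3 WT arrays are too few to split, so part of the excess in the same direction may come from the shared controls. Shared controls would not give the excess of genes lower in G609G and higher in LCS.

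Single probe sets were also tested against the other probe sets of their gene, which asks whether parts of a transcript changed apart from the whole. diffSplice called 24525 of 156218 probe sets in G609G minus WT, 2841 in LCS minus WT and 28469 in G609G minus LCS. Of these calls 7806, 1337 and 9031 lay in genes with a fold under 1.5, and the splicing index called 19047, 1329 and 23653 probe sets. Tested within the genes of a fold under 1.5 alone, 6461, 1001 and 7526 were called. The LCS minus WT count was 1879 without LCS replicate 3, 4901 without the intensity filter, 1346 with the filter at the 50th percentile, 5302 from the WT and LCS arrays alone and 4305 by an unmoderated, unadjusted comparison at a fold of 1.5. The G609G minus LCS count was 18749 without LCS replicate 1 and 18890 without LCS replicate 3. Among the probe sets with the lowest p in G609G minus WT, Ryr1 5234597 changed by -0.23 while its other probe sets had a median of 5.52, and Adam28 4824172 by 1.09 against -6.00. Muc5b 4464446 changed by 0.48 against -4.83. These Ryr1, Adam28 and Muc5b probe sets were bright in all groups and moved far less than their gene. Their means in WT, G609G and LCS were 8.92, 8.69 and 8.76 for Ryr1 and 11.15, 12.24 and 11.51 for Adam28. For Muc5b they were 8.37, 8.85 and 8.39. Such probe sets do not follow their gene, so their calls do not show that a part of the transcript changed. In Abcc9, 4897360 rose by 4.90 while the others had a median of 0.35, and in Itpr2, 4773041 by 2.74 against -1.02. In LCS minus WT the probe sets were Eif4g1 4531764 (2.97 against 0.26), Lmna 5039122 (-4.37 against 0.13), Prmt5 5140061 (4.15 against 0.24), Muc5b 4464446 (0.02 against -3.11) and Enpp1 4814205 (-4.75 against -2.08). The Dst probe set 5009506 changed by -3.97 in G609G minus LCS against -1.38 for its others. These probe sets passed the splicing index test too, with adjusted p of at most 0.024. A probe set that does not follow its gene can pass that test as well, so the pass does not set the cases apart. On simulated data for G609G minus WT, 306 of the diffSplice calls, 71.8%, were false, against 1 with the splicing index. Only 68, 66 and 66 probe sets carried planted changes of 0.5, 1 and 2 there. That share therefore does not carry over to the 24525 calls above, of which a part may be false too.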

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

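Tests chosen only after the result was seen were the fits without the filter on dim genes and the relative median for muscle, the spread among epididymal genes, and each test of the adipose transcripts; the relative scale itself was also chosen then. Several gene lists were called in opposite directions in the mutants against WT, and the direct test of G609G minus LCS passed with camera at the preset correlation. The deposited median difference between the mutants was -0.71 for mature adipocyte (-0.69 in G609G and 0.13 in LCS against WT), -0.91 for lipolysis (-0.79 and 0.17), -1.62 for macrophage (-1.22 and 0.38), -1.36 for adipocyte progenitor and fibroblast (-0.95 and 0.47) and -1.66 for extracellular matrix (-1.23 and 0.46). For oxidative phosphorylation it was -0.10 (-0.13 and -0.04): camera, which compares the list with other genes, called it higher in G609G against the sign of its median, and lower in LCS. The direct tests had adjusted p = 0.000155, 0.00218, 1.72e-05, 0.00407, 1.52e-05 and 0.00373 in this order. With an estimated correlation the direct tests gave adjusted p = 0.495 for the first 5 and 0.712 for oxidative phosphorylation.

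Probe sets without a single gene symbol, which no comparison above uses, also differed from WT. Of 12960 tested as deposited, 1530 were higher and 4941 lower in G609G, and 767 higher and 1108 lower in LCS. Their deposited median log2 fold was -0.27 in G609G and 0.00 in LCS. The highest was probe set 4676875 in G609G, at a log2 fold of 5.90.

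The skeletal muscle transcripts that were higher in G609G may come from muscle tissue in these samples. In a second list of 38 muscle genes, none of them in the first, 28 were measured and fitted without the filter on dim genes, since a rise in G609G can itself lift a gene over it, and 89.3% lay above 1 relative to the median gene, as this explanation needs; Tnnt3 reached a mean of 13.27 in G609G, and 7 of the 28 had a WT mean over 6. Brown adipocytes, which share some muscle genes, are argued against as the whole cause: fitted in the same way, 25 brown and beige genes had a median of 0.50 and at most 2.79 relative to the median gene, under the muscle list's lower quartile of 4.50, and the G609G means of Ucp1, Dio2, Elovl3 and Otop1 were 4.51, 5.03, 5.14 and 4.73. Those G609G means alone do not say whether Dio2, Elovl3 and Otop1 rose or fell against WT, while Ucp1 was lower than in WT, as given above. Dio2, Elovl3 and Otop1 were also named after their values were seen. A uniform shift from the authors' normalization is argued against by the muscle list's median of 6.55 relative to the median gene. The scaling offset of -0.46 lowers G609G, so this outcome was known before the test. A shift that varies with intensity was not tested, here or for the transcripts below. Whether muscle came in at dissection or belongs to the tissue in this genotype stays open and untested.

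Germ cell transcripts were lower in both mutants and epididymal transcripts differed: of 14 tested genes of a second germ cell list 14 fell in G609G (median -1.55, relative to the median gene -1.09) and 12 in LCS (median -1.86), and without the filter on dim genes 23 of 26 fell in each (medians -1.06 and -0.96), while of 18 epididymal genes 15 fell and 2 rose in G609G and 7 fell and 8 rose in LCS. In LCS, a uniform shift is argued against by the 11 germ cell genes with a WT mean over 6, whose median was -2.42 relative to the median gene. Less testis tissue in the LCS samples could not be decided, since of 2 tested Leydig cell genes only Hsd3b6 had such a WT mean (-2.79, and -2.50 in G609G), and Star, at a WT mean of 5.30, went the other way in LCS (0.41, adjusted p = 0.00417, and -0.07 in G609G, adjusted p = 0.494). Without the filter on dim genes, 5 Leydig cell genes were measured. Of these, 3 fell and 1 rose in LCS (median -0.74). In G609G 4 fell and 0 rose as deposited (median -0.41, relative to the median gene 0.05). In G609G, a single lower share of epididymis is argued against by 16 epididymal genes, whose log2 folds had an interquartile range of 4.46, from Lcn8 at -8.15 to Crisp1 at 0.11. Epididymal transcripts were abundant in every group: in WT, G609G and LCS, Crisp1 averaged 12.73, 12.84 and 11.11 and Lcn5 13.38, 11.48 and 11.86. Epididymal tissue may thus be present in the samples of every group. Members did not move as a single set. Genes with large falls in G609G, such as Lcn8, Cst11 and Rnase10 (-8.15, -6.65 and -6.18), did not fall in LCS (0.34, 0.50 and 1.32). The 7 that fell in LCS changed in G609G by -3.26 (Defb21) to 0.11 (Crisp1). Among these, Spink8 changed by -0.51 in G609G and -2.21 in LCS. What sets these genes apart was not tested. Testis tissue in the WT samples may be a source of the germ cell transcripts, and an effect of genotype stays open and untested.

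Adipocyte, stromal and macrophage transcripts were lower in G609G. Dilution of adipose RNA by other RNA was weighed on 7 adipocyte genes with a WT mean of 9 to 12. Their log2 folds had an interquartile range of 1.20. This argues against dilution by RNA that lacks these transcripts as the whole cause, since that, like a uniform shift, lowers such genes alike. Dilution by RNA that holds some of these transcripts could lower them unequally and was not tested. These genes do not bear on dilution of the macrophage and extracellular matrix transcripts. For the macrophage and extracellular matrix lists, a uniform shift from the normalization as the whole cause is also argued against by medians of -0.75 and -0.77 relative to the median gene and -0.60 and -0.61 with arrays centred on the tested genes, with upper quartiles under 0 on both scales. The medians of the adipocyte progenitor and fibroblast list (-0.48 and -0.33) and the mature adipocyte list (-0.23 and -0.07, against -0.69 as deposited) decide nothing, since members go both ways on these scales (16 lower and 4 higher, and 14 lower and 6 higher, relative to the median gene). A uniform shift may account for part of the falls, and dilution for part or all of them. An effect of the genotype stays open and untested.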

How the results depend on the processing

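Settings added after seeing the data were both added scalings, the splicing index and the replicate block on WT and G609G alone. Counts of changed genes for G609G minus WT, LCS minus WT and G609G minus LCS were 5058, 965 and 5370 by the methods' t-test at its threshold, 5028, 942 and 5340 by it after Benjamini-Hochberg adjustment, and 5095, 973 and 5392 with limma at a fold of at least 1.5, where the added fold limit lowers them. With array weights LCS minus WT rose to 6376; the cause was not tested. Camera's list counts became 3, 0 and 2 with an estimated correlation, and fry, which asks another question, gave 32, 21 and 32, or 35 each in either direction. For probe sets, LCS minus WT became 4901 without the filter and 1346 with the 50th percentile (other numbers tested), 5302 from only the 2 groups compared, 4305 by a Student comparison and 1329 by the splicing index; the cause was not tested. Only genes with a fold under 1.5 gave 6461, 1001 and 7526; fewer are tested (76655, 135601 and 73314), and calls were rarer there, 7806, 1337 and 9031 when adjusted over all probe sets. Lmna probe sets called became 1 (G609G minus WT) and 7 (G609G minus LCS) with the 50th percentile, 0 and 0 where Lmna's own fold excludes it, and 3 (LCS minus WT) by the splicing index.

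Leaving out 1 array gave 8674 to 9121, 3204 to 3826 and 8596 to 9117 genes, 17840 to 31115, 1879 to 2366 and 18749 to 34977 probe sets, 17 to 18, 11 to 12 and 15 to 17 lists, 2 to 4, 9 to 12 and 8 to 11 Lmna probe sets, and 1240 to 1758 genes changed alike in both mutants. Moves over 1.5 times came without LCS replicate 3 (1879 in LCS minus WT, 18890 in G609G minus LCS) and without LCS replicate 1 (18749 in G609G minus LCS).

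Directions reversed for few named genes. Lmna in LCS minus WT was -0.47 with plain means, and in G609G minus WT 0.014 with arrays centred on the tested genes. Pparg and Pnpla2 in G609G minus WT became 0.20 and 0.14 with quantile normalization, 0.50 and 0.50 with arrays centred on all probe sets, 0.47 and 0.48 centred on the tested genes, and 0.32 and 0.33 relative to the median gene. In G609G minus LCS they became 0.38 and 0.11, 0.67 and 0.43, 0.64 and 0.42, and 0.49 and 0.28. For Pparg and Pnpla2 the scaling shifts G609G as a whole. For Lmna, LCS minus WT folds were -4.37, -2.57 and -2.08 at probe sets 5039122, 4479405 and 4817758. The largest rise was 0.79, at 5114835. A plain mean gives such low probe sets more weight than a median polish does. Of the other named gene results under alternatives, 2034 kept direction and side of the threshold, 77 lost and 9 gained a call. Each setting with a fold limit of 1.5, where smaller folds cannot pass, gave 18 of the lost calls.

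Over the 3 groups, correlations of same-numbered deviations ran from -0.12 to 0.34, 6 of 9 over 0.1, and 2 of 9 arrays correlated best with their own number; LCS shares only a number with the others. With the replicate block the counts were 9189, 4429 and 9224 genes, 27726, 3297 and 32064 probe sets, 18, 12 and 17 lists, 3, 12 and 11 Lmna probe sets, and 1644 shared genes. With the replicate block on WT and G609G alone they were 9211 genes, 23973 probe sets, 15 lists and 4 Lmna probe sets; the lists lost were lipolysis, oxidative phosphorylation and adipocyte progenitor and fibroblast, Cidea lost its call and Lmna probe set 5549630 gained one, and no other named call of that comparison changed.

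Each 6 arrays make 10 splits, too few for a share under 0.05; 1 of 10, the real one, gave as many calls. Fitted on those arrays, the real and highest other values were 8772 and 0, 5052 and 0, and 8965 and 0 genes, 18441 and 48, 5302 and 441, and 25385 and 76 probe sets, and 17 and 14, 12 and 10, and 16 and 12 lists. In G609G minus WT the other splits that part every same-numbered pair gave at most 0 genes, 18 probe sets and 11 lists. Every other split holds both genotypes on each side in unequal shares. It therefore keeps part of the real difference and widens the spread within sides, so its values are no chance level. Low intensities limit dim genes: those under 5.09 on average were not tested.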

Other observations

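Replicates lay close together: the median SD of a gene within a group was 0.08 in WT, 0.12 in G609G and 0.06 in LCS on the log2 scale.

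Interferon response genes were lower in G609G than in LCS in 23 of 24 cases, also adjusted over the list alone, and 16 relative to the median gene. The camera adjusted p was 0.0447, and adjusted p = 0.712 with an estimated correlation. Cholesterol synthesis genes fell in G609G against WT in 16 of 18 cases as deposited and adjusted over the list alone, and 14 relative to the median gene, without a camera call (adjusted p = 0.262). Of 33 splicing factor genes 26 were higher and 3 lower relative to the median gene, while 6 were higher and 14 lower as deposited (6 and 13 adjusted over the list alone), with a median of -0.13; camera called the list higher (adjusted p = 0.00495, and adjusted p = 0.737 with an estimated correlation).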
